A study of Brassica napus with 48 samples.

How the data were processed

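RNA of 48 samples of Brassica napus flower buds was measured on Affymetrix Arabidopsis ATH1 arrays, a short-oligonucleotide platform designed for another species of the same family. Plants grew in a field. Per the labels' protocols, total RNA was extracted with Trizol, purified on RNeasy columns, and turned into biotin-labelled cRNA. The deposited values are signal intensities on a linear scale, made with MAS5 per the submitters' processing notes; its version is not given in the sources used here. In the deposited table each array had a 2% trimmed mean of 500.0, so arrays had been scaled to a common mean intensity before deposit. Median signal per array ran from 339 to 410.1. Detection calls and probe-level values were not used here. No column of per-sample values was left unused.

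The table held 22810 probe sets, of which 64 were array controls. The given annotation paired 13513 probe sets with 1 gene and 503 with several. A further 8730 were unnamed here, and no gene was named from a probe set with several. Arabidopsis names stand for the probe set designed for that gene. Rapeseed RNA with a mismatched sequence binds such a probe less well, so a signal compares samples for 1 probe set and never probe sets with each other. A probe set can also bind several rapeseed copies of a gene. Where J10 and J03 differ in these sequences or copies, a signal can differ between the lines without a change in expression. This was not tested.

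Samples fell into 12 groups by line, fertility and bud size class. Each group had 4 arrays, titled biol_rep or tech_rep with the number 1 or 2. A tech_rep array was taken here as the second hybridisation of the biological replicate with its number. The titles do not state this, and the array correlations of J03 did not bear it out. On this reading, which all replicate means and spreads rest on, each group had 2 biological replicates with 2 hybridisations each. The labels do not say which plants made up each replicate, so p-values measure only the spread between these replicates. The number of arrays limits the precision. Signals were changed to log2 values after adding an offset of 113.0, the median over arrays of their 25th percentile. Changes on this scale understate those of dim probe sets. Probe sets entered the test if their mean signal reached the array median (50th percentile) in both replicates of at least 1 group. This kept 14023 probe sets, 7848 of them with 1 gene, 282 with several and 5893 unnamed here. The 2 hybridisations of a replicate were averaged, which left 24 columns.

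The moderated linear model of limma 3.58.1 in R 4.3.3 was fitted to all 12 groups together (12 residual degrees of freedom, intensity trend on), and 25 comparisons were taken from it. They were sterile against fertile within each line and size class, the line difference and the stage difference of that effect, J10 against J03, and successive size classes. P-values were adjusted by Benjamini-Hochberg within each comparison and called at an adjusted p under 0.05. Chance alone gives 701 probe sets with an unadjusted p under 0.05. Adjusted p-values in the text are limma's unless another test is named. Overlaps of calls were tested with Fisher's exact test, which takes probe sets as independent. Array measures were compared between groups with 2-sided permutation tests, exact where a group held under 10 values, as 1 family of 21 tests. Sterile and fertile samples were also compared within same-numbered replicates by exact sign-flip permutation, added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

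Before the data were examined, 15 gene lists with 329 Arabidopsis genes were fixed. They covered tapetum and early anther regulators, pollen wall and tapetum enzymes, pollen coat proteins, meiosis, maturing pollen, and jasmonate and anther dehiscence. Others covered pistil and ovule markers, floral identity, photosynthesis, phenylpropanoids, heat shock, defence, senescence proteases, abscisic acid, and sugar import. The annotation named 70 of the 329 members and 51 were tested, so most lists rest on few members and 11 had at least 2. Another 4 lists (plastid-encoded genes, mitochondrion-encoded genes, tubulins, further pollen genes) were defined after the annotation and array quality were seen, but before any group was fitted. List shifts were tested with camera at a preset correlation of 0.01, and again with a correlation estimated per list. That made 375 list tests; 42 were called, of which 7 held with the estimated correlation. The lists were also tested with fry.

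Named genes followed a rule fixed beforehand. For sterile against fertile, it took the 5 one-gene probe sets with the largest change in each direction, among calls where both sterile replicates lay on the same side of both fertile ones. It added up to 3 called members of each list and a set of anther marker genes named always; of those only AMS and A9 were named in the annotation and tested. For the other comparisons it took 3 per direction and up to 2 per list.

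Alternatives chosen beforehand were quantile normalization, no offset or a doubled one, no filter or a stricter one, a required log2 change of 1, the first hybridisation of each replicate only, and all 48 arrays with the replicate as a random block. The rest were a replicate block, a fit to the compared groups only, and leaving out each biological replicate in turn. In the last, the remaining replicate of a group is assumed to vary like the other groups. Settings added after seeing the data left out 1 or 3 arrays that were least like their groups, took hybridisation number as a fixed block, took the RNA 3' to 5' ratio as a covariate, or took replicate number as a block separately in each line.

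The procedure was tested on simulated data with 200 changed probe sets in each of 3 simulations over 14023 probe sets. Values were independent normal draws with the spread of each probe set around a mean common to all 12 groups. They held no correlation of genes, no component shared by replicates and no difference in 3' to 5' ratio. The rates below are therefore those of ideal data and do not bear on such effects. In the large J10 comparison it recovered 34.3% of changes of log2 size 1 and 86.0% of size 2, with 3.99% of calls false. In the small J03 comparison it recovered 30.7% and 90.3%, with 5.71% of calls false. No changed probe set was called with the wrong sign.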

Results

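Flower buds of oilseed rape (Brassica napus) were profiled in 2 lines, J10 and J03, in which dominant genic male sterility segregates. Per the labels, sterile J10 plants were MsMsrfrf and fertile ones MsMsRfrf, whereas sterile J03 plants were Msmsrfrf and fertile ones msmsrfrf. Plants therefore differed at Rf within J10 and at Ms within J03. Small buds (under 1 mm), middle buds (1 to 3 mm) and large buds (over 3 mm) stood for the tetrad, uninucleate and trinucleate pollen stages, and each bud held stamens and pistils. The 48 arrays made 12 groups, each with 2 biological replicates hybridised 2 times by the reading of the titles used here. Levels are the signal of the probe set designed for an Arabidopsis gene, as mean ± SD over the 2 replicates. Changes are on the log2(signal + offset) scale with their SE, and n = 2 in every group unless another n is given.

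Arrays of a group correlated with r of 0.657 to 0.861 (median 0.801, across probe sets), against a median of 0.741 between groups, and no pair of arrays was identical. The ratio of 3' to 5' signal, averaged over the actin, GAPDH and ubiquitin control transcripts, served as a stand-in for RNA integrity, which was not measured directly. The controls are Arabidopsis probe sets, so the ratio may also reflect mismatches or which rapeseed copies bind. It was higher in J10 than in J03 (mean log2 ratio 1.48 ± 0.374 against 0.998 ± 0.185, n = 12, permutation p = 0.00097, adjusted p = 0.0068). Within J10 it was higher in sterile than in fertile samples (1.75 ± 0.179 against 1.21 ± 0.308, n = 6, exact permutation p = 0.0022, adjusted p = 0.011). In J03 the sterile and fertile samples had 1.05 ± 0.185 and 0.943 ± 0.183 (n = 6, exact permutation p = 0.303, adjusted p = 0.442). Each control alone was also higher in J10 and in sterile J10 samples, but not each passed. Between lines the adjusted permutation p was 0.0018 for actin, 0.189 for GAPDH and 0.026 for ubiquitin. Between sterile and fertile J10 samples the adjusted exact permutation p was 0.2045, 0.034 and 0.026 in that order. The median of plastid-encoded transcripts, an added list, was also higher in J10 than in J03 (11.73 ± 0.414 against 10.84 ± 0.445, n = 12, permutation p = 0.00017, adjusted p = 0.0018). It was higher in sterile than in fertile J10 samples by 0.55 (n = 6, exact permutation p = 0.0087, adjusted p = 0.026). In J03 that difference was 0.39 (n = 6, exact permutation p = 0.134, adjusted p = 0.217). These tests take same-numbered replicates as unrelated, although those of J10 deviated together. Within same-numbered replicates of a size class, the ratio was higher in sterile J10 buds in 6 of 6 pairs (exact sign-flip permutation p = 0.0312, the smallest 6 pairs can give) and in sterile J03 buds in 5 of 6 (exact p = 0.0625). Plastid medians were higher in 5 of 6 pairs in J10 (exact sign-flip p = 0.0625) and in J03 (exact sign-flip p = 0.219), so the plastid call within J10 was lost in this form. The sign-flip tests take the 6 pairs of a line as independent, although same-numbered J10 replicates also deviated together across size classes.

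**Figure D1:**
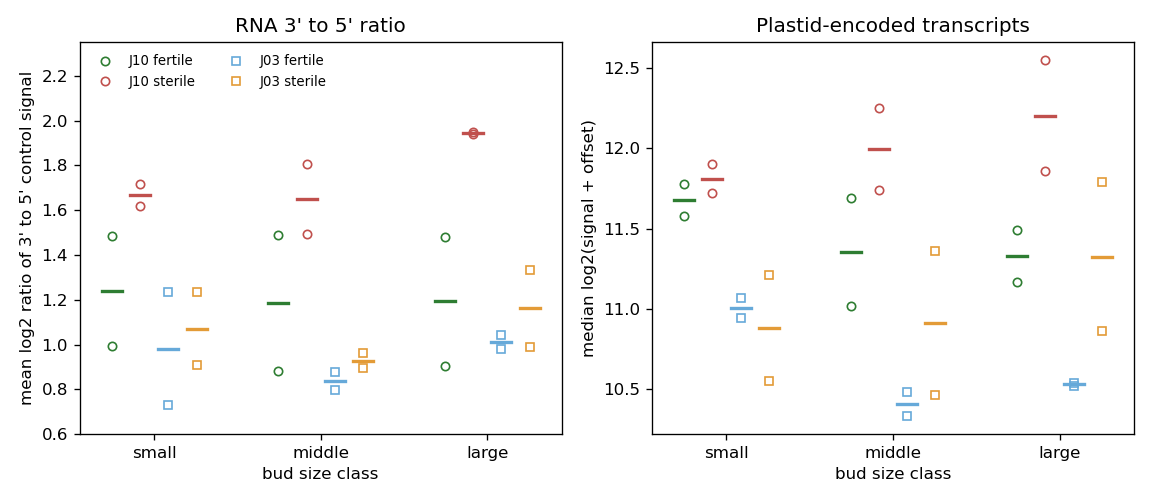
The left panel plots the mean log2 ratio of 3' to 5' control signal, and the right panel the median log2(signal + offset) of plastid-encoded probe sets, by bud size class; points are biological replicates and bars are means. In large buds both sterile J10 replicates lie above every other replicate of that class in both panels, with a mean ratio 0.751 above that of fertile J10 buds.

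The first question was how sterile buds differed from fertile ones of the same line and stage. In small J10 buds most called transcripts were lower in sterile plants. AT1G56220, of the dormancy/auxin-associated family, fell from 3029 ± 343 in fertile to 643 ± 86.0 in sterile buds (log2 change -2.07, SE 0.31, adjusted p = 0.0022). AT5G62360, of the invertase and pectin methylesterase inhibitor family, fell from 1331 ± 95.1 to 240 ± 162 (-2.16, SE 0.41, adjusted p = 0.029). AT4G27450 and AT3G15450 fell as well (-1.49, SE 0.29, and -1.05, SE 0.20), with adjusted p of 0.031 and 0.029. AT1G62500, of the lipid transfer protein family, rose from 5006 ± 50.8 to 12083 ± 344 (1.27, SE 0.23, adjusted p = 0.026), and AT5G15950, an S-adenosylmethionine decarboxylase, by 1.59 (SE 0.31, adjusted p = 0.036). The tapetal genes AMS and A9 had changes of 0.24 (SE 0.27, adjusted p = 0.943) and -0.11 (SE 0.26, adjusted p = 0.972). In all 15 probe sets were called by limma, 2 higher and 13 lower in sterile buds, and 1012 had an unadjusted p under 0.05. Without sterile replicate 1 or 2 the count was 5 or 7, and without fertile replicate 1 or 2 it was 2 or 17; each named change lost its call without fertile replicate 1 (adjusted p up to 0.615 over the settings tried). AT1G62500 and AT4G27450 lost theirs without any 1 of the 4 replicates, AT3G15450 and AT5G15950 also without either sterile replicate, AT5G62360 without either replicate 2, and AT1G56220 without sterile replicate 1. Other settings gave 3 calls with first hybridisations only, 50 with all 48 arrays and the replicate as a random block, and 5 with the 3' to 5' ratio as a covariate. All 6 named changes lost their calls with first hybridisations only, and all but AT1G56220 with the covariate.

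In middle J10 buds the largest changes were falls, with a gene of the tapetum, the cell layer that feeds developing pollen, among them. AT2G03740, of the late embryogenesis abundant (LEA) family, fell from 6124 ± 794 in fertile to 258.5 ± 90.2 in sterile buds (-4.18, SE 0.31, adjusted p = 1.7e-08). SHT, the tapetal spermidine hydroxycinnamoyl transferase, fell from 7330 ± 1301 to 860 ± 315 (-2.98, SE 0.36, adjusted p = 9.0e-05). Also lower were AT4G00040, of the chalcone and stilbene synthase family (-2.52, SE 0.39, adjusted p = 0.0011), AT4G29250, of the acyltransferase family that includes SHT (-2.27, SE 0.36, adjusted p = 0.0016), and AT5G65205 (-2.16, SE 0.35, adjusted p = 0.0023). Of the 8 tested pollen wall and tapetum enzymes 1 fell, SHT (2 adjusted over the list alone), with a list median of -0.37. AMS (0.13, adjusted p = 0.932) and A9 (-0.62, adjusted p = 0.443) passed no threshold. Among higher transcripts AT4G02920 rose by 1.77 (SE 0.35, adjusted p = 0.014), AT4G03100 by 1.49 (SE 0.35, adjusted p = 0.047), AT5G52030 by 1.42 (SE 0.31, adjusted p = 0.034), AT1G62500 by 1.03 (SE 0.23, adjusted p = 0.040), and plastid psbL by 1.24 (SE 0.29, adjusted p = 0.044). In total 80 probe sets were called (11 higher, 69 lower), and 1298 had an unadjusted p under 0.05. With a replicate block within each line, added after seeing the data, small, middle and large J10 buds each had over 1.5 times the reported number of calls.

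The 5 lower genes of middle J10 buds kept their calls in all 18 settings, except that AT5G65205 lost it without sterile replicate 1 (adjusted p = 0.064). AT4G02920, AT4G03100 and AT5G52030 lost theirs without any 1 of the 4 replicates, and psbL and AT1G62500 without sterile replicate 1 or either fertile replicate (adjusted p up to 0.207, 0.374, 0.67, 0.416 and 0.425 over the settings tried). All 5 of these higher genes also lost their calls with the compared groups only and with the 3' to 5' ratio as a covariate. AT4G03100 was called in 4 and AT5G52030 in 9 of 17 settings. Leaving out sterile replicate 1 or 2 gave 63 or 50 calls, and fertile replicate 1 or 2 gave 43 or 41. Fitting the compared groups only gave 30 calls and all 48 arrays 153, with 34 under the 3' to 5' covariate and 130 without the array that was least like its group, which lies among the sterile ones here.

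Large J10 buds held 341 calls, the most of the 6 sterile-fertile comparisons as fitted, but with the 3' to 5' ratio as a covariate they held 79 and large J03 buds 137. AT3G23770, of a beta-1,3-glucanase family, rose from 287.5 ± 38.7 in fertile to 16540.5 ± 3811 in sterile buds (5.44, SE 0.78, adjusted p = 0.00013). A9, a tapetum gene, rose from 1617 ± 783 to 4556 ± 527 (1.51, SE 0.26, adjusted p = 0.0012), although it lost its call without fertile replicate 1 (adjusted p = 0.075). AT3G07840, of the polygalacturonase family, fell from 2365 ± 1122 to 122.0 ± 21.3 (-3.35, SE 0.44, adjusted p = 5.2e-05), and AT4G16190, a papain-type cysteine protease, from 40513 ± 2241 to 3582 ± 572 (-3.45, SE 0.24, adjusted p = 6.1e-09). The LEA family members AT2G03740, AT3G02480 and AT5G53820 fell (-3.48, SE 0.31; -3.31, SE 0.40; -2.90, SE 0.40) at adjusted p of 1.8e-07, 1.8e-05 and 7.3e-05. SHT (-2.40, SE 0.36, adjusted p = 0.00022) and the tetraspanin gene TET11 (-1.48, SE 0.29, adjusted p = 0.0043) fell too, and AMS had -0.55 (SE 0.27, adjusted p = 0.363). All called genes named here except A9 and TET11 kept their calls in all 18 settings; TET11 lost its call without sterile replicate 1 or fertile replicate 2, with first hybridisations only and with the covariate (adjusted p up to 0.159 over the settings tried).

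In large J10 buds 5 of 65 plastid and 1 of 13 mitochondrial genes were called higher in sterile plants, and neither list shift held with an estimated correlation (adjusted p = 0.414 and 0.537). Plastid psbL rose by 2.26 (SE 0.29, adjusted p = 3.1e-05), psbA by 2.18 (SE 0.46, adjusted p = 0.0078), petL by 1.76 (SE 0.35, adjusted p = 0.0050) and mitochondrial nad4 by 1.97 (SE 0.38, adjusted p = 0.0043). With the 3' to 5' ratio as a covariate psbL kept its call and the other 3 lost it. They also lost it without sterile replicate 1, psbA without fertile replicate 2, and petL and nad4 without fertile replicate 1 (adjusted p up to 0.2 for psbA, 0.187 for petL and 0.346 for nad4 over the settings tried). In this comparison limma called 341 probe sets, 70 higher and 271 lower, and 1961 had an unadjusted p under 0.05. The count was 125 or 245 without sterile replicate 1 or 2, and 122 or 238 without fertile replicate 1 or 2. It was 176 with first hybridisations only and 554 with all 48 arrays.

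Sterile and fertile buds of J03 differed in few probe sets before the large stage. In small buds 1 probe set was called, unnamed here and singled out after its values were seen; it rose from 154.5 ± 18.9 to 1136 ± 86.6 (2.26, SE 0.35, adjusted p = 0.013). In middle buds 4 fell. The shaggy-like protein kinase gene AT3G61160 went from 2578 ± 344 in fertile to 974.8 ± 232 in sterile buds (-1.33, SE 0.23, adjusted p = 0.033). The other 3 are unnamed here; they had -2.85, -1.76 and -1.53 (SE 0.52, 0.29 and 0.27, adjusted p = 0.043, 0.033 and 0.043). AMS and A9 had changes of -0.27 and -0.57 in small buds (SE 0.27 and 0.26, adjusted p = 0.938 and 0.687). Their middle-bud values were 0.20 and 0.27 (adjusted p = 0.997 and 0.978). Unadjusted p-values under 0.05 numbered 972 in small and 789 in middle buds. No small-bud call was left without sterile replicate 1 or either fertile replicate (limma, 0 calls; 948, 740 and 752 unadjusted), and the count stayed at 1 without sterile replicate 2. In middle buds most or all calls were lost whichever of the 4 replicates was left out, and AT3G61160 did not keep its call across these fits. All 48 arrays gave 30 calls in small and 10 in middle buds.

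In large J03 buds most called transcripts were lower in sterile plants, genes of maturing pollen among them. AT3G07840, the polygalacturonase family gene, fell from 3964 ± 843 in fertile to 114.8 ± 45.7 in sterile buds (-4.13, SE 0.44, adjusted p = 5.3e-06), and AT5G53820, of the LEA family, from 2523 ± 1100 to 89.1 ± 3.8 (-3.70, SE 0.40, adjusted p = 5.3e-06). AT1G52680 (-3.11, SE 0.42, adjusted p = 0.00012), AT1G63060 (-2.90, SE 0.39, adjusted p = 0.00012) and the aspartyl protease gene AT4G04460 (-2.42, SE 0.38, adjusted p = 0.00092) fell as well. Of 6 tested members of the maturing pollen list 2 fell (2 adjusted over the list alone): ACT12, the pollen actin, from 1159 ± 118 to 158 ± 51.9 (-2.33, SE 0.47, adjusted p = 0.0094), and AT5G45880, of the pollen Ole e 1 family (-2.04, SE 0.38, adjusted p = 0.0051). TET11 (-1.69, SE 0.29, adjusted p = 0.0021) and UPEX1 (AT1G33430), which encodes a galactosyltransferase of pollen wall formation (-1.104, SE 0.24, adjusted p = 0.019), were lower too. AMS and A9 had -0.59 (adjusted p = 0.512) and 0.51 (adjusted p = 0.595).

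Among transcripts higher in large sterile J03 buds, AT1G12010, an ACC oxidase of ethylene synthesis, rose from 1299 ± 42.9 to 5482 ± 429 (1.98, SE 0.20, adjusted p = 2.4e-06). The metallothionein MT1C rose by 1.90 (SE 0.40, adjusted p = 0.012), AT1G05340 by 1.91 (SE 0.43, adjusted p = 0.023), AT5G61820 by 1.85 (SE 0.34, adjusted p = 0.0043) and plastid psbM by 2.27 (SE 0.53, adjusted p = 0.032). AT1G12010 and the 5 genes with the largest falls kept their calls in all 18 settings. AT1G05340 and psbM lost their calls without any 1 of the 4 replicates (adjusted p up to 0.199 and 0.31 over the settings tried). ACT12, UPEX1 and MT1C lost theirs without sterile replicate 1 or either fertile replicate (up to 0.139, 0.363 and 0.286). AT5G45880 lost it without sterile replicate 2 or fertile replicate 1, AT5G61820 without either replicate 1, and TET11 without sterile replicate 1 or fertile replicate 2 (up to 0.212, 0.116 and 0.089). In all 135 probe sets were called, 29 higher and 106 lower, with 1250 at an unadjusted p under 0.05. The count was 54 or 105 without sterile replicate 1 or 2, and 49 or 50 without fertile replicate 1 or 2; first hybridisations only gave 65 and all 48 arrays 202.

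**Figure D2:**
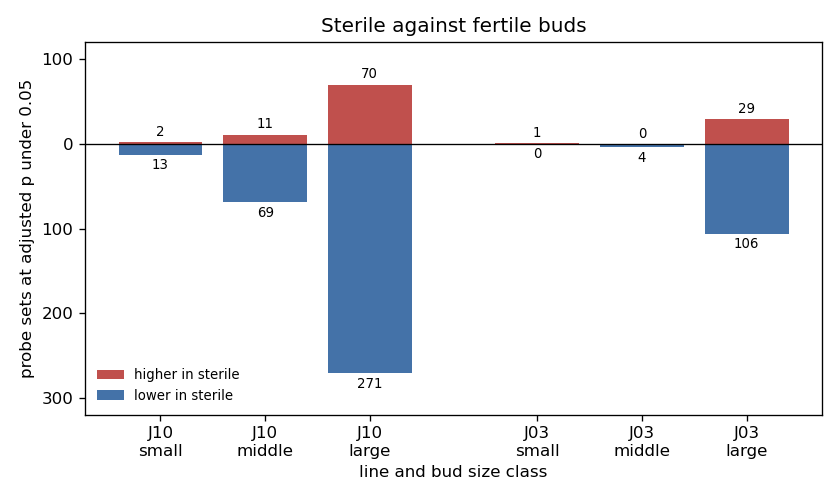
Bars give the number of probe sets called higher or lower in sterile than in fertile buds (adjusted p under 0.05), for each line and bud size class, from 0. Large buds have the most calls in both lines, 271 lower and 70 higher in J10, 106 lower and 29 higher in J03.

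The lower calls of large buds were shared between the lines more often than independent lists would give. Of 271 in J10 and 106 in J03, 62 were common to both, against 2.05 for independent lists (Fisher's exact p = 2.3e-80), and none was called in opposite directions. Probe sets are not independent, and 1 estimate of spread per probe set served both lines, so Fisher's p-values here may be too small. AT3G07840, AT5G53820 and TET11 were among those named in both lines. Of the 106 J03 calls, 103 also had a negative change in J10. Higher calls shared 1 probe set of 70 and 29 (0.145 for independent lists, Fisher's exact p = 0.135). By sign, 22 of the 29 J03 calls and 56 of the 70 J10 calls also had a positive change in the other line. Over all probe sets the changes of both lines correlated with r = 0.336 in large buds, 0.0859 in middle and 0.0775 in small buds, across probe sets that are not independent. Middle buds shared 1 lower call of 69 and 4 (0.0197 for independent lists, Fisher's exact p = 0.020), and small buds shared none. With the 3' to 5' ratio as a covariate the lower overlap in large buds was 35.

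A test of the line difference itself called few probe sets whose sterile-fertile change differed between J10 and J03. Its SE was larger than that of a sterile-fertile comparison (0.44 against 0.31 for AT2G03740 in middle buds), and the simulations did not cover it. Few calls therefore do not show that the lines responded alike. In middle buds AT2G03740 differed by -3.03 (SE 0.44, adjusted p = 0.0055): it went from 11685 ± 1761 to 5279 ± 1606 in J03 and from 6124 ± 794 to 258.5 ± 90.2 in J10. AT4G28240 differed by -1.77 (SE 0.31, adjusted p = 0.030), and 2 unnamed here by -2.34 and -2.45 (SE 0.40 and 0.42, adjusted p = 0.027 for both). In large buds AT4G16190 differed by -2.56 (SE 0.34, adjusted p = 0.0017), with the protease transcript at 18969 ± 47.7 in sterile J03 buds. The vacuolar ATPase subunit gene AT4G02620 differed by -1.64 (SE 0.29, adjusted p = 0.036). The other 2 of the 4 calls of large buds are unnamed here, singled out after their values were seen (2.92, SE 0.47, and -2.99, SE 0.42), at adjusted p of 0.010 and 0.0019. Pollen wall and tapetum enzymes as a list shifted by a median of -0.75 in middle buds (camera adjusted p = 0.0022), with 0 of 8 called and adjusted p = 0.233 with an estimated correlation.

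In small buds limma called 0 such differences, with 812 at an unadjusted p under 0.05, against 942 for the 4 of middle and 1066 for the 4 of large buds. AT4G16190 kept its call in all 22 settings. AT2G03740 lost it without sterile replicate 1 or fertile replicate 1 of J10 and without sterile replicate 2 or fertile replicate 1 of J03 (adjusted p up to 0.174 over the settings tried). AT4G28240 and AT4G02620 kept theirs in 11 and 12 of 22 settings, and AT4G02620 lost it with the 3' to 5' covariate. Leaving out 1 replicate gave 0 or 1 call in small buds, 0 to 13 in middle buds (13 without J10 sterile replicate 2) and 2 to 17 in large buds (17 without J10 sterile replicate 2). The settings with all 48 arrays as a random block gave 8, 17 and 31 calls.

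The sterile-fertile difference also changed between small and large buds. In J10 it moved up for AT3G23770 by 5.30 (SE 1.11, adjusted p = 0.021), for AT1G36990 by 2.25 (SE 0.47, adjusted p = 0.021), for the aspartyl protease family gene AT5G10770 by 2.02 (SE 0.37, adjusted p = 0.0081), for psbL by 1.77 (SE 0.41, adjusted p = 0.039) and for A9 by 1.62 (SE 0.37, adjusted p = 0.037). It moved down for AT5G53820 (-3.72, SE 0.56, adjusted p = 0.0011), for AT2G03740 (-3.54, SE 0.44, adjusted p = 9.6e-05), for AT3G02480 (-3.35, SE 0.57, adjusted p = 0.0040) and for SHT (-2.36, SE 0.51, adjusted p = 0.025). In J03 it moved up for the pectin methylesterase gene ATPMEPCRD (3.34, SE 0.61, adjusted p = 0.0078), MT1C (3.31, SE 0.56, adjusted p = 0.0044) and AT5G40690 (2.86, SE 0.59, adjusted p = 0.026). It moved down for AT3G07840 (-4.27, SE 0.63, adjusted p = 0.00089), AT5G53820 (-3.49, SE 0.56, adjusted p = 0.0028) and AT1G52680 (-3.31, SE 0.59, adjusted p = 0.0075). Limma called 85 probe sets in J10 (20 up, 65 down) and 51 in J03 (16 up, 35 down). Without 1 replicate the counts ran from 37 (J10 fertile large replicate 1) to 60 and from 26 (J03 fertile small replicate 2) to 45; AT3G23770 lost its call without any of the 8 replicates (adjusted p up to 0.107), whereas AT2G03740, AT5G53820 in J10 and AT3G07840 kept theirs in all 22 settings. In J10, A9, psbL and SHT lost theirs with the 3' to 5' covariate and were called in 10, 10 and 11 of 22 settings.

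**Figure D3:**
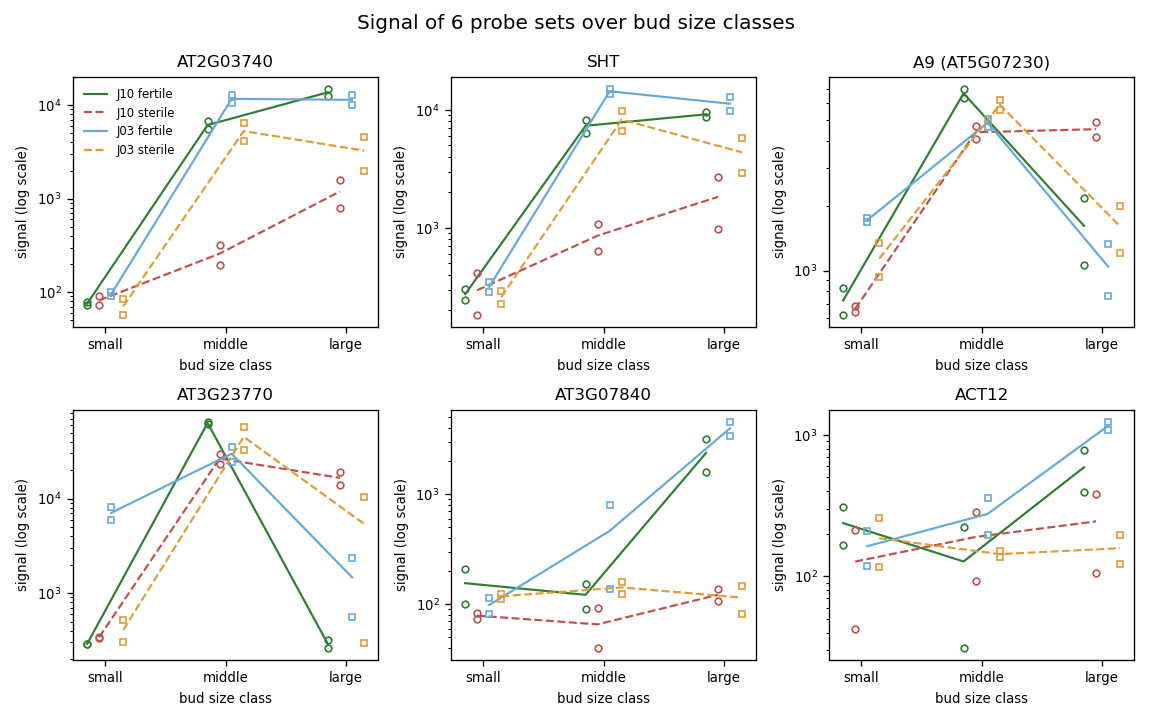
Signal on a log axis over the bud size classes for the probe sets of AT2G03740, SHT, A9 (AT5G07230), AT3G23770, AT3G07840 and ACT12; points are biological replicates, lines join group means, solid for fertile and dashed for sterile plants of each line. AT3G07840 stands at 2365 and 3964 in large fertile buds and at 122.0 and 114.8 in large sterile buds of J10 and J03.

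Few members of the fixed anther lists were called between sterile and fertile buds. The 5 tapetum and early anther regulators had no call in any of the 6 comparisons (2 adjusted over the list alone; medians -0.57 to 0.20; lowest camera adjusted p = 0.127). The 8 pollen wall and tapetum enzymes had 4 calls (11 adjusted over the list alone), namely SHT in middle and large J10 buds, A9 in large J10 buds and UPEX1 in large J03 buds. Their camera shift in middle J10 buds (adjusted p = 0.017) was lost with an estimated correlation, at adjusted p = 0.476. The 6 maturing pollen genes had 2 calls (2 adjusted over the list alone; lowest camera adjusted p = 0.073), and the 10 further pollen genes, an added list, 2 (4 adjusted over the list alone; lowest camera adjusted p = 0.096). No call fell on the 4 pollen coat proteins (medians -0.44 to 0.71), 3 meiosis genes (-0.31 to 0.23), 6 pistil and ovule markers (-0.08 to 0.23) or 3 members of the phenylpropanoid list (-0.53 to 0.17). Of the last 3, CHI was matched by its symbol alone, which different genes can share, so its probe set may not be that of the intended gene. None fell on 2 heat shock genes (-0.68 to 0.31), 4 senescence proteases (-0.23 to 0.26), 3 sugar import genes (-0.14 to 0.10) or 6 tubulins (-0.21 to 0.16). Adjusted over the list alone, 1 member of the phenylpropanoid list passed, and no member of the other 7 lists just named. The lowest camera adjusted p of these lists was 0.150. Jasmonate, defence and abscisic acid lists had 1 tested member each, JMT, PDF1.2 and COR15A, with lowest adjusted p of 0.627, 0.461 and 0.671, and no floral identity gene was tested.

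The 4 photosynthesis genes, markers of green tissue, had a median of -0.55 in small sterile J10 buds, with 0 called (2 adjusted over the list alone; camera adjusted p = 0.011, but adjusted p = 0.498 with an estimated correlation). Of 65 plastid-encoded genes 55 lay above 0 in large sterile J10 buds (5 called higher, 16 adjusted over the list alone, median 0.52, camera adjusted p = 1.3e-09). In large J03 buds 64 did (1 called higher, 2 adjusted over the list alone, median 0.64, camera adjusted p = 1.1e-17). Middle buds had medians of 0.30 in J10 (1 called; camera adjusted p = 4.1e-05) and 0.17 in J03 (0 called; camera adjusted p = 0.0011). With an estimated correlation these 4 plastid shifts had adjusted p = 0.414, 0.278, 0.423 and 0.731. The 13 mitochondrion-encoded genes shifted by medians of 0.31 in middle and 0.35 in large J10 buds (0 and 1 called; camera adjusted p = 0.043 and 0.030), with adjusted p = 0.423 and 0.537 with an estimated correlation. The 3' to 5' ratio was higher in sterile than in fertile buds by 0.43, 0.464 and 0.751 in small, middle and large J10 buds. In large J03 buds it was higher by 0.151.

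Lines were compared next at equal fertility and stage. Sequence or copy differences between the lines could also change the signal of a probe set, so higher or lower here refers to signal. In middle sterile buds AT2G03740 was lower in J10 (258.5 ± 90.2 against 5279 ± 1606 in J03; -3.96, SE 0.31, adjusted p = 5.2e-08), as were SHT (860 ± 315 against 8268 ± 2271; -3.14, SE 0.36, adjusted p = 1.0e-05) and AT5G65205 (-2.64, SE 0.35, adjusted p = 8.8e-05). In small buds AT1G56220 (-2.30, SE 0.31, adjusted p = 0.00033), AT2G32150 (-2.46, SE 0.40, adjusted p = 0.0015) and AT5G05600, a jasmonate oxygenase (-2.16, SE 0.42, adjusted p = 0.0081), were lower in J10. AT4G22120 (2.19, SE 0.39, adjusted p = 0.0035) and AT3G10610 (1.95, SE 0.38, adjusted p = 0.0080) were higher. In middle buds AT3G53890 (2.102, SE 0.41, adjusted p = 0.0057) and AT1G48330 (2.09, SE 0.37, adjusted p = 0.0021) were higher in J10. In large buds J10 was lower for MT1C (629 ± 18 against 5728 ± 2595; -2.83, SE 0.40, adjusted p = 0.00023), AT1G73600, of the phosphoethanolamine methyltransferase family (-2.54, SE 0.37, adjusted p = 0.00028), and AT4G16190 (-2.36, SE 0.24, adjusted p = 3.6e-06). It was higher for A9 (1.55, SE 0.26, adjusted p = 0.0010) and for AT3G23770 (3.01, SE 0.78, adjusted p = 0.037), whose sterile J03 replicates lay far apart (5401 ± 7224). TUA6 was higher by 0.78 (SE 0.19, adjusted p = 0.027).

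Of 4 nuclear photosynthesis genes 2 were called lower in sterile J10 than in sterile J03 buds at each stage, in a comparison where J10 had the higher 3' to 5' ratio. RCA, the Rubisco activase, was lower in J10 at the small, middle and large stage (log2 changes -1.14, -1.16 and -1.33, SE 0.22, adjusted p = 0.0083, 0.0052 and 0.0011). PRK, the phosphoribulokinase, had -1.04, -1.15 and -1.18 (SE 0.24, adjusted p = 0.026, 0.0094 and 0.0064). The photosynthesis list had medians of -0.87, -0.72 and -0.65, with 2 of 4 called each time (2 adjusted over the list alone) and camera adjusted p of 0.00080, 0.0047 and 0.016. With an estimated correlation its adjusted p = 0.281, 0.353 and 0.605. Of 65 plastid-encoded genes 3, 7 and 4 were called, all higher in J10 (10, 19 and 16 adjusted over the list alone; medians 0.63, 0.75 and 0.53; camera adjusted p = 1.4e-11, 2.4e-16 and 2.9e-08). With an estimated correlation these had adjusted p = 0.453, 0.321 and 0.638. Among them rps19 was higher by 1.83, 2.22 and 2.17 (SE 0.43, adjusted p = 0.029, 0.0052 and 0.0052), rps2 in small buds by 1.84 (SE 0.43, adjusted p = 0.030), rpl14 in middle buds by 2.01 (SE 0.54, adjusted p = 0.046) and psbL in large buds by 2.53 (SE 0.29, adjusted p = 1.4e-05). Mitochondrial nad4 was higher in middle buds by 1.498 (SE 0.38, adjusted p = 0.037). Under the 3' to 5' covariate RCA and PRK lost their calls at all 3 stages (adjusted p up to 0.263 and 0.398 over the settings tried); rps19 in small and large buds, rps2 and nad4 lost theirs too, whereas psbL in large and rps19 and rpl14 in middle buds kept theirs. Without any 1 of the 4 replicates RCA, PRK and rps2 lost their small-bud calls. In middle buds RCA lost its call without J03 replicate 2, PRK without J10 replicate 2 or either J03 replicate, and rpl14 and nad4 without J10 replicate 1 or either J03 replicate. PRK and rps19 in large buds lost theirs without J10 replicate 1 or J03 replicate 2, and rps19 also in small buds (J10 replicate 1 or either J03 replicate) and middle buds (either replicate 1). Adjusted p reached 0.267 for rps2, 0.414 for rpl14, 0.516 for nad4 and 0.308 for rps19.

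In sterile buds 175, 335 and 372 probe sets were called at the small, middle and large stage (46, 96 and 139 higher in J10, 129, 239 and 233 lower). Leaving out J10 replicate 1 or 2 and J03 replicate 1 or 2 gave 54, 67, 101 and 36 in small buds. The same gave 183, 234, 146 and 68 in middle buds and 117, 240, 197 and 163 in large buds. With the 3' to 5' ratio as a covariate the counts were 46, 78 and 64, and with all 48 arrays 319, 517 and 587. With that covariate AT3G10610 in small buds, AT3G53890 and AT1G48330 in middle buds, and AT3G23770, TUA6 and AT1G73600 (adjusted p = 0.0628) in large buds lost their calls. AT1G56220 in small buds, AT2G03740, SHT and AT5G65205 in middle buds, and MT1C, AT4G16190, A9 and psbL in large buds kept their calls in all 18 settings. AT3G23770 lost its call without either J10 replicate or J03 replicate 1 (adjusted p up to 0.641 over the settings tried). In small buds AT5G05600 lost it without either J10 replicate or J03 replicate 2, AT4G22120 and AT3G10610 without J10 replicate 1 or J03 replicate 2, and AT2G32150 without J03 replicate 2 (up to 0.235, 0.0876, 0.159 and 0.0608). In middle buds AT3G53890 lost it without J10 replicate 1 or J03 replicate 2 and AT1G48330 without J03 replicate 2, and in large buds TUA6 did without either replicate 1 (up to 0.185, 0.107 and 0.268).

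Fertile buds of the lines were compared in the same way. In small buds AT3G23770 stood at 7064 ± 1564 in J03 and at 289.7 ± 1.8 in J10 (-4.14, SE 0.78, adjusted p = 0.014). PORB, the protochlorophyllide oxidoreductase, was higher in J10 (4174 ± 399 against 1600 ± 15.5; 1.33, SE 0.20, adjusted p = 0.0014), as were AT1G48330 (1.67, SE 0.37, adjusted p = 0.039) and AT4G30650 (1.62, SE 0.35, adjusted p = 0.035). AT2G32150 (-2.12, SE 0.40, adjusted p = 0.014) and AT5G05600 (-2.10, SE 0.42, adjusted p = 0.026) were lower in J10. AT4G30650 stayed higher in middle and large buds (2.29 and 2.22, SE 0.35, adjusted p = 0.0016 and 0.0027). AT1G73600 was lower in both (-2.08 and -2.67, SE 0.37, adjusted p = 0.0063 and 0.00064), and in middle buds AT4G33660 (-2.03, SE 0.31, adjusted p = 0.0016) and AT4G10260, a fructokinase (-1.93, SE 0.43, adjusted p = 0.038). In large buds AT5G45880 (-1.93, SE 0.38, adjusted p = 0.016) and AT5G05600 (-1.90, SE 0.42, adjusted p = 0.038) were lower in J10.

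Of 65 plastid-encoded genes 0, 3 and 3 were called in small, middle and large fertile buds, all higher in J10. They included rpl33 by 2.70 and 2.99 (SE 0.54, adjusted p = 0.016 and 0.0089) and rps18 by 2.50 and 2.12 (SE 0.49, adjusted p = 0.014 and 0.044) in middle and large buds. The list had medians of 0.45, 0.75 and 0.65 (camera adjusted p = 4.2e-08, 1.3e-15 and 2.1e-15), with adjusted p = 0.493, 0.638 and 0.513 with an estimated correlation. In fertile buds 55, 80 and 79 probe sets were called at the small, middle and large stage (29, 44 and 59 higher in J10, 26, 36 and 20 lower). Leaving out J10 replicate 1 or 2 and J03 replicate 1 or 2 gave 17, 21, 8 and 15 in small, 55, 37, 39 and 16 in middle, and 40, 17, 4 and 33 in large buds. Without any 1 of the 4 replicates rpl33 and rps18 lost their calls (adjusted p up to 0.164 and 0.283 over the settings tried), and in small buds AT3G23770, AT1G48330, AT4G30650 and AT5G05600 did too (up to 0.143, 0.356, 0.543 and 0.202), as did AT4G10260 in middle buds (up to 0.32). AT2G32150 in small and AT1G73600 in middle buds lost theirs without J10 replicate 2 or either J03 replicate (up to 0.245 and 0.11). In large buds AT5G45880 and AT5G05600 did without either J10 replicate or J03 replicate 1, and AT4G30650 without either replicate 1 (up to 0.4, 0.557 and 0.0632). PORB lost its call with first hybridisations only (adjusted p = 0.0657). With the 3' to 5' covariate AT1G48330 in small, AT4G10260 in middle and rps18 in large buds lost theirs; AT4G10260 was called in 7 and rps18 in large buds in 9 of 18 settings. First hybridisations only gave 9, 31 and 22 calls, and all 48 arrays 181, 157 and 148; AT4G30650 and AT4G33660 in middle and AT1G73600 in large buds kept their calls in all 18 settings.

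Stages were compared within each kind of plant. From small to middle buds AT3G23770 rose in fertile J10 from 289.7 ± 1.8 to 63095 ± 3155 (7.28, SE 0.78, adjusted p = 1.8e-06), in sterile J10 from 341 ± 7.1 to 26533 ± 4357 (5.85, SE 0.78, adjusted p = 0.00026) and in sterile J03 by 6.42 (SE 0.78, adjusted p = 1.3e-05). AT2G03740 rose by 5.04, 5.81 and 4.85 in fertile J10, fertile J03 and sterile J03 (SE 0.31, adjusted p = 3.0e-10, 1.3e-11 and 7.0e-10), and SHT by 4.26, 5.10 and 4.57 (SE 0.36, adjusted p = 4.6e-08, 1.6e-09 and 1.6e-08). In sterile J10 buds, looked up after these values were seen, AT2G03740 stood at 81.8 ± 12.8 in small and 258.5 ± 90.2 in middle buds, and SHT at 296.4 ± 162.2 and 860 ± 315. A9 rose in all 4 kinds of plant, by 3.03 in fertile J10, 2.52 in sterile J10, 1.44 in fertile J03 and 2.29 in sterile J03 (SE 0.26, adjusted p = 4.6e-08, 1.4e-05, 0.0015 and 5.2e-06). AMS, a tapetal bHLH regulator, rose in fertile J10 by 1.13 (SE 0.27, adjusted p = 0.025) and in sterile J03 by 1.29 (SE 0.27, adjusted p = 0.0080), and ATA27 in the same plants by 1.97 and 2.32 (SE 0.44, adjusted p = 0.015 and 0.0032). AMS also stood higher in middle than in small buds of sterile J10 (1889.5 ± 79.5 against 875.1 ± 22.3) and fertile J03 (1979.8 ± 107.9 against 1091.5 ± 258.6). The 8 pollen wall and tapetum enzymes had medians of 1.29, 1.13, 0.96 and 1.48 in fertile and sterile J10 and fertile and sterile J03, with 3, 2, 3 and 4 called higher (6, 5, 5 and 6 adjusted over the list alone). With an estimated correlation adjusted p = 0.0012, 0.0044, 0.051 and 0.0037, so the shift was lost in fertile J03.

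Further changes were named from small to middle buds. In sterile J10, the aspartyl protease family gene AT1G25510 rose by 2.64 (SE 0.38, adjusted p = 0.00053), AT4G30470 by 2.58 (SE 0.35, adjusted p = 0.00026) and the lipid transfer protein gene AT5G52160 by 2.41 (SE 0.56, adjusted p = 0.047). In fertile J03, AT5G65205 rose by 4.67 (SE 0.35, adjusted p = 5.7e-09) and TET11 by 1.28 (SE 0.29, adjusted p = 0.011). AT1G12010, the ACC oxidase, fell in fertile J10 from 5477 ± 643 to 774 ± 56.6 (-2.63, SE 0.20, adjusted p = 1.4e-08), and AT1G56220 fell by 1.92 (SE 0.31, adjusted p = 0.00043). AT4G28703 had -1.98, -1.79 and -2.09 in fertile J10, sterile J10 and fertile J03 (SE 0.39, adjusted p = 0.0042, 0.027 and 0.0018). In sterile J10, AT2G46540 (-1.43, SE 0.28, adjusted p = 0.012) and the ribosomal protein gene AT1G52300 fell (-1.28, SE 0.24, adjusted p = 0.010). GID1B, a gibberellin receptor, fell in fertile and sterile J03 (-2.53 and -2.01, SE 0.37, adjusted p = 0.00014 and 0.0024). AT5G57785 fell by 2.11 in fertile J03 (SE 0.27, adjusted p = 1.5e-05), and in sterile J03 AT5G05600 (-2.05, SE 0.42, adjusted p = 0.0067) and AT1G80750 (-1.82, SE 0.44, adjusted p = 0.027).

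From small to middle buds 217 probe sets were called in fertile J10 (154 higher, 63 lower), 77 in sterile J10 (51 and 26), 424 in fertile J03 (244 and 180) and 281 in sterile J03 (180 and 101). Without small replicate 1 or 2 and middle replicate 1 or 2, fertile J10 had 168, 159, 208 and 140, and sterile J10 had 24, 31, 145 and 31. Fertile J03 had 162, 224, 235 and 191 in that order, and sterile J03 135, 144, 158 and 102. AT3G23770, AT2G03740, SHT, A9, AT1G12010 and AT5G65205 kept their calls in all 18 settings of each of these comparisons. AMS lost its call in fertile J10 without small or middle replicate 2, and in sterile J03 without either replicate 2 (adjusted p up to 0.443 and 0.162 over the settings tried). ATA27 lost it in fertile J10 without either replicate 2 and in sterile J03 without middle replicate 1 (up to 0.355 and 0.0629). AT4G28703 lost it in fertile J10 without small replicate 2 or middle replicate 1, in fertile J03 without small replicate 1, and in sterile J10 without any 1 of the 4 replicates (up to 0.284, 0.0575 and 0.267).

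In sterile J10, AT5G52160 also lost its small to middle call without any 1 of the 4 replicates, AT2G46540 without either small replicate or middle replicate 2, and AT1G52300 without either replicate 2 or with quantile normalization (adjusted p up to 0.316, 0.292 and 0.632). In fertile J03, TET11 lost it without either small replicate or middle replicate 2 (up to 0.279). In sterile J03, GID1B lost it without middle replicate 1, AT5G05600 without either replicate 2, and AT1G80750 without either small replicate or middle replicate 1 (up to 0.071, 0.215 and 0.33).

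From middle to large buds of fertile J10, AT3G07840 rose from 121.8 ± 43.0 to 2365 ± 1122 (3.36, SE 0.44, adjusted p = 6.3e-05), AT4G04460 by 3.16 (SE 0.38, adjusted p = 2.5e-05) and AT3G02480 by 3.12 (SE 0.40, adjusted p = 5.0e-05). In fertile J03, AT1G52680 rose by 3.17 (SE 0.42, adjusted p = 0.00017), AT3G07840 by 3.05 (SE 0.44, adjusted p = 0.00029), AT1G63060 by 2.92 (SE 0.39, adjusted p = 0.00017) and AT5G45880 by 2.37 (SE 0.38, adjusted p = 0.0012). AT3G23770 fell in fertile J10, fertile J03 and sterile J03 (-7.37, -4.47 and -4.43, SE 0.78, adjusted p = 3.4e-06, 0.0030 and 0.0051). AT3G52130 and AT5G52160, which encode anther lipid transfer proteins, fell in fertile J10 (-4.21 and -3.82, SE 0.53 and 0.56, adjusted p = 3.9e-05 and 0.00020). They fell in fertile J03 (-2.90 and -2.50, adjusted p = 0.0038 and 0.025) and in sterile J03 (-3.46 and -3.84, adjusted p = 0.0013 and 0.00093). AT1G76470 fell in fertile J03 (-3.51, SE 0.69, adjusted p = 0.0080).

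Fewer probe sets were called from middle to large buds in sterile than in fertile plants of each line; the difference in number was not tested. In sterile J10 the named changes were AT2G03740, which rose from 258.5 ± 90.2 to 1194.5 ± 558 (1.85, SE 0.31, adjusted p = 0.011), AT3G52130, which fell by 3.06 (SE 0.53, adjusted p = 0.013), the sugar transporter gene SWEET3, which fell by 2.26 (SE 0.31, adjusted p = 0.0029), and AT3G07450, which fell by 2.15 (SE 0.40, adjusted p = 0.022). In sterile J03, AT5G05600 rose by 2.69 (SE 0.42, adjusted p = 0.0014), MT1C from 964 ± 85.4 to 5728 ± 2595 (2.297, SE 0.40, adjusted p = 0.0046) and AT1G18810 by 2.25 (SE 0.43, adjusted p = 0.0096). The pollen wall and tapetum enzymes had medians of -0.65, -0.42 and -1.17 in fertile J10, fertile J03 and sterile J03, with 3, 3 and 4 called lower (4, 3 and 5 adjusted over the list alone). With an estimated correlation adjusted p = 0.028, 0.016 and 0.0042. The tapetum and early anther regulators fell as a list in sterile J03 (median -0.69, 0 of 5 called, 2 adjusted over the list alone; camera adjusted p = 0.00013, and adjusted p = 0.0056 with an estimated correlation).

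From middle to large buds 158 probe sets were called in fertile J10 (101 higher, 57 lower), 10 in sterile J10 (3 and 7), 114 in fertile J03 (77 and 37) and 66 in sterile J03 (26 and 40). Without middle replicate 1 or 2 and large replicate 1 or 2, fertile J10 had 159, 87, 69 and 143. In that order fertile J03 had 32, 76, 31 and 88, and sterile J03 43, 8, 11 and 103. Sterile J10 had 1 and 12 without middle replicate 1 or 2, 11 without large replicate 1 and 0 without large replicate 2 (limma; 895 unadjusted); all 4 genes named for it lost their calls without large replicate 2 or middle replicate 1 (adjusted p up to 0.352, 0.303, 0.078 and 0.4 over the settings tried). In fertile plants AT3G07840, AT4G04460, AT3G02480, AT1G52680 and AT1G63060 kept their calls in all 18 settings. AT3G23770 lost its J03 calls without fertile middle or large replicate 1 (adjusted p up to 0.165) and without sterile middle replicate 2 or large replicate 1 (adjusted p up to 0.166). In fertile J03, AT1G76470 lost its call without either middle replicate or large replicate 1 (-4.81 to -2.22 over the settings tried, adjusted p up to 0.456). AT3G52130 and AT5G52160 lost theirs without middle replicate 1 or either large replicate, and AT5G45880 without either replicate 1 (up to 0.121, 0.443 and 0.114). In sterile J03, AT3G52130, AT5G05600 and MT1C lost theirs without middle replicate 2 or large replicate 1, AT5G52160 without large replicate 1, and AT1G18810 without either middle replicate or large replicate 1 (up to 0.106, 0.142, 0.242, 0.0868 and 0.35). In sterile J10, AT3G52130 and AT3G07450 also lost theirs without middle replicate 2, and AT3G07450 with the 3' to 5' covariate.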

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

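The tests of RNA quality and of green tissue were chosen after the results they bear on were seen. The tests of delayed development, and of RNA quality as its cause, were written before their medians were computed, although levels of A9 and AT3G23770 had been seen.

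Among 48 checks of 4 arrays each (12 groups, 4 measures), 5 had an array far from the other 3, where chance gives about 1 in 20. Replicate 2, hybridisation 2 of middle sterile J10 buds had a mean correlation of 0.667 with its group and 18.8% of signals under the offset. The same hybridisation of large sterile J10 buds had 0.746 and 20.6%. Replicate 1, hybridisation 2 of small fertile J03 buds had a mean correlation of 0.783. Without these 3 arrays large J10 buds had 392 calls instead of 341, and the middle line difference fell from 4 to 0 (limma; 982 unadjusted).

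The sterile-fertile difference differed between lines, by the interaction term of limma, for 4 probe sets in middle and 4 in large buds. These included AT2G03740 (-3.03) and AT4G28240 (-1.77) in middle buds, and AT4G16190 (-2.56) and AT4G02620 (-1.64) in large buds. In middle buds AT2G03740 lost its call without J10 sterile replicate 1, J10 fertile replicate 1, J03 sterile replicate 2 or J03 fertile replicate 1 (adjusted p from limma over 0.05 each time). It also lost it without the 3 arrays and with first hybridisations only (adjusted p = 0.174). AT4G28240 lost its call without any replicate but J10 sterile replicate 2, and AT4G02620 without any but J03 fertile replicate 2 (adjusted p up to 0.366 and 0.282), whereas AT4G16190 was called in all 22 settings.

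Between small and large buds the difference changed for 85 probe sets in J10 and 51 in J03, again by an interaction term. In J10 the named genes were AT3G23770 (5.30), AT1G36990 (2.25), AT5G10770 (2.02), psbL (1.77), A9 (1.62), SHT (-2.36), AT3G02480 (-3.35), AT2G03740 (-3.54) and AT5G53820 (-3.72). In J03 they were ATPMEPCRD (3.34), MT1C (3.31), AT5G40690 (2.86), AT1G52680 (-3.31), AT5G53820 (-3.49) and AT3G07840 (-4.27). Without replicate 1 or 2 in turn the J10 count was 48 or 45 (sterile small), 56 or 44 (fertile small), 48 or 60 (sterile large) and 37 or 58 (fertile large). The J03 count was 30 or 30 (sterile small), 27 or 26 (fertile small), 42 or 45 (sterile large) and 27 or 31 (fertile large).

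In J10, AT3G23770 lost its stage-difference call without any 1 of the 8 replicates, A9 without any but fertile large replicate 2, and psbL without any but sterile large replicate 2. SHT lost it without any but sterile small replicate 1 and sterile large replicate 2 (adjusted p up to 0.107, 0.271, 0.287 and 0.412 for the 4 genes over all settings). AT1G36990 lost it without sterile small or sterile large replicate 2, either fertile small replicate or fertile large replicate 1, and AT5G10770 without fertile small replicate 1 or fertile large replicate 2 (up to 0.158 and 0.0994). In J03, AT5G40690 lost it without any but sterile small and fertile large replicate 2, and ATPMEPCRD without sterile or fertile small replicate 2 (up to 0.183 and 0.0857). No single replicate ended the other stage-difference calls named above.

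A9 and AT3G23770 were higher in large sterile than in large fertile J10 buds, which led to the hypothesis that these lag in development, although AT3G52130, which falls in fertile buds, also fell by 3.06 in sterile J10. The 37 probe sets that fell from middle to large fertile J03 buds were chosen on other plants. They include AT3G23770, whose J10 change had already been seen and which was not removed. In large J10 buds the 37 had a median sterile-fertile change of 0.91, and the 77 that rose had -1.11. For the 37, the median ran from 0.59 to 1.14 over 4 replicate pairs, and 32 were above 0 but 10 called higher. Lower RNA quality as the cause predicted at least 0.26 in small and 0.281 in middle J10 buds, but the medians were -0.079 (pairs -0.207 to 0.17) and -0.613. The change thus did not follow the ratio over the size classes. An opposite effect of sterility in small and middle buds could hide one of RNA quality, so this test cannot exclude it. A delay may be a candidate explanation, while other effects of sterility on the same transcripts stay untested. In J03 the matching median was 0.368 over 57 probe sets. The rule set beforehand took a median under 0.1 in at least 2 of 4 pairs as the outcome without a delay. It was met, although the pairs straddled the bound (-0.123 to 0.792). The 57 changed from middle to large buds by -1.19 in sterile and -1.13 in fertile J03, which also goes against a delay. The 101 that rose had -1.03, which a delay predicts but other effects of sterility could give as well. By its rule, a delay was therefore not borne out in J03. With pairs on both sides of the bound and 44 of the 57 above 0, this test cannot exclude one either.

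The RNA 3' to 5' ratio was higher in sterile than in fertile J10 buds, so RNA quality could lie behind calls made in large J10 but not in large J03 buds. In step with the smaller ratio difference of J03 (0.151 against 0.751), the 209 lower probe sets would change there by -0.243 and the 69 higher ones by 0.265; their medians were -0.349 (pairs -0.453 to -0.187) and 0.419 (pairs 0.328 to 0.388). The bounds had been set at 2 times these values (-0.487 and 0.53), but the probe sets were chosen for having no call in J03, which keeps their change there small, so medians inside the bounds decide nothing. With the ratio as a covariate the median of all 271 lower calls went from -1.38 to -1.12, all kept their sign and 63 kept their call, while the median SE rose from 0.279 to 0.345; the 70 higher ones went from 1.32 to 1.26 with 11 called (SE 0.308 to 0.403). RNA quality and sterility cannot be told apart for these probe sets, because the ratio differed with the groups.

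Plastid-encoded transcripts were higher in J10 than in J03, by 0.885 over all buds. Within groups the 12 replicate differences in 3' to 5' ratio and in plastid level had r = -0.0439 about 0 (exact sign-flip permutation p = 0.874) and a rank value of 0.0154 (p = 0.968, exact sign-flip), and r = 0.306 without the 2 largest ratio differences; these tests take the 12 as independent, although same-numbered J10 replicates were related. At its upper 95% end the slope predicted a line difference of 0.448 on the log2 scale. This lay above the required limit of 0.442, so RNA quality cannot be told apart from line. More green tissue in J10 would raise nuclear photosynthesis genes, whose median was below 0 in 5 of 6 comparisons but 0.112 in fertile middle buds, on 4 genes. A genetic difference between the lines stays untested.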

How the results depend on the processing

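Settings that left out 1 or 3 arrays, took hybridisation number as a fixed block, took the 3' to 5' ratio as a covariate, or took a replicate block within each line were chosen after seeing the data; the others were planned. Without a filter and with a required log2 change of 1, all 25 counts stayed within 1.5 times the reported count. The number moved further was 3 with quantile normalization, 4 without offset, 2 with the doubled offset, 4 with a stricter filter, 4 with a replicate block, 5 each without the 1 or the 3 arrays and 8 with the covariate. It was 20 with all 48 arrays, 20 with first hybridisations only, 19 with the compared groups only, 21 with all 48 arrays and the hybridisation block, and 18 with a replicate block within each line. Of 168 named calls none reversed; 3 were lost with quantile normalization, 31 without offset, 0 with the doubled offset, 16 without filter, 2 of 153 with a stricter filter, 1 with all 48 arrays, 61 with first hybridisations only and 0 with the replicate block. The compared groups alone lost 30, the 3 arrays 7, the 1 array 4, the hybridisation block 1 and the covariate 38, and 99 were lost without at least 1 replicate. Of 42 list shifts 7 were kept with an estimated correlation, 10 with fry (18 shifts in all, from 42), 38 with quantile normalization, 40 without offset, 40 with the replicate block, 35 without the 3 arrays, 37 without the 1 array and 29 with the covariate. Signals under the offset made up 18.8 to 26.9% of an array, where small changes of dim probe sets were not detectable. The cause of each shift below was not tested, except that fewer arrays or fewer groups leave less information by construction, and that counting both hybridisations as separate arrays adds residual degrees of freedom.

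In what follows, sterile-fertile counts are given as J10 small, middle, large and J03 small, middle, large (reported 15, 80, 341 and 1, 4, 135), line differences of that effect by size (0, 4, 4), and stage differences for J10 and J03 (85, 51). Line counts are sterile (175, 335, 372) and fertile (55, 80, 79). Stage counts are middle against small and large against middle buds, for fertile J10 (217, 158), sterile J10 (77, 10), fertile J03 (424, 114) and sterile J03 (281, 66).

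With all 48 arrays as a random block, the correlation of hybridisations was 0.0433. Sterile-fertile counts were 50, 153 and 554 in J10 and 30 and 10 in small and middle J03 buds, line differences 8, 17 and 31, and stage differences 133 and 95. Line counts were 319, 517 and 587 (sterile) and 181, 157 and 148 (fertile). Stage counts were 337 in fertile J10 (middle against small), 145 and 21 in sterile J10 and 116 in sterile J03 (large against middle).

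With all 48 arrays and also hybridisation number as a fixed block, a change of 2 choices, the sterile-fertile counts were 53, 159 and 566 and 33, 12 and 206, line differences 14, 16 and 39, and stage differences 138 and 93. Line counts were 338, 510 and 595 (sterile) and 192, 163 and 155 (fertile). Stage counts were 329 in fertile J10 (middle against small), 144 and 21 in sterile J10 and 110 in sterile J03 (large against middle). Calls common to both lines rose from 64 to 108 in all, to 6 in small buds (1 higher, 5 lower), 3 in middle buds (3 lower) and 99 in large buds (8 higher).

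With first hybridisations only, the J10 counts were 3, 40 and 176 and the large J03 count 65. Line differences were 0 in middle (limma; 924 unadjusted) and 1 in large buds, and stage differences 32 and 25. Line counts were 84, 156 and 211 (sterile) and 9, 31 and 22 (fertile). Stage counts were 134 and 83 in fertile J10, 39 and 5 in sterile J10, 253 in fertile J03 (middle against small) and 43 in sterile J03 (large against middle). AMS in middle J10 buds turned from 0.13 to -0.0382 and A9 in middle J03 buds from 0.27 to -0.0506, neither called.

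Fitting only the compared groups gave 8, 30 and 198 in J10 and 19 and 20 in small and middle J03 buds, line differences 1, 17 and 2, and a J10 stage difference of 45. Line counts were 141 and 209 (sterile, middle and large) and 26, 46 and 51 (fertile). Stage counts were 130 and 78 in fertile J10, 42 in sterile J10 (middle against small) and 652 and 206 in fertile J03.

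With the 3' to 5' ratio as a covariate the J10 counts were 5, 34 and 79, the small J03 count 9, the small line difference 1 and the sterile line counts 46, 78 and 64. Shared calls were 37 in all, 1 in small buds (1 lower) and 35 in large buds (0 higher, 35 lower).

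Without the 1 array least like its group the counts were 130 (J10 middle), 6 and 2 (J03 small and middle), 1 (line difference, middle) and 560 (sterile lines, middle). Shared calls were 2 in small buds (1 higher, 1 lower), 0 in middle buds (0 lower) and 0 higher in large buds. Without the 3 arrays they were 0 and 2 (J03 small and middle; limma, 1031 unadjusted in small buds), 0 (line difference, middle; 982 unadjusted), 564 (sterile lines, large) and 88 (fertile lines, small). Shared calls were 0 in middle buds (0 lower) and 2 higher in large buds.

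Quantile normalization gave 7 for small J03 buds (2 higher, 5 lower, against 1 and 0), 8 for the large line difference and 86 for the small fertile lines. Its middle line difference split 1 higher and 5 lower, against 0 and 4; shared calls were 4 in small buds (4 lower) and 2 higher in large buds. Without offset the counts were 3 (J03 small), 56 and 27 (stage differences) and 74 (fertile J03, large against middle), with 0 shared calls in middle buds (0 lower). The doubled offset gave 2 (J03 small), 7 (large line difference) and 0 higher calls shared in large buds. A stricter filter gave 5 and 2 (J03 small and middle), 9 (large line difference) and 86 (fertile lines, small).

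The labels number the replicates alike in every group without saying that a number marks a shared origin. Deviations of same-numbered replicates correlated with a median of 0.0255 over 66 pairs of groups (-0.0782 to 0.293). Within J10, however, the median was 0.181 (0.0944 to 0.293, over 0.1 in 14 of 15 pairs), and within J03 0.0168 (-0.044 to 0.0796, 0 of 15). Fertile J10 replicate 1 had 3' to 5' ratios of 0.992, 0.883 and 0.905 across sizes and replicate 2 had 1.48, 1.49 and 1.48. Sterile J10 ratios did not follow the number (1.619, 1.805 and 1.948 in replicate 1, 1.717, 1.496 and 1.939 in replicate 2). By the correlations of deviations, the number in J10 went with a shared component of unknown origin, which the reported fit left in the error. The reported fit required a value over 0.1 in every pair, and so did not pair the samples. With 14 of 15 J10 pairs over 0.1 and the lowest at 0.0944, missing that requirement does not show the J10 replicates to be unrelated. A replicate block within each line gave higher J10 sterile-fertile counts, listed below. The fit with 1 replicate block over both lines gave 8 for small J03 buds, 13 and 10 for the middle and large line differences and 91 for the small fertile lines, and left the other 21 counts within 1.5 times.

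With a replicate block within each line the sterile-fertile counts were 28, 161 and 575 in J10 and 18 and 9 in small and middle J03 buds, line differences 9, 17 and 35, and the J03 stage difference 84. Line counts were 334, 557 and 629 (sterile) and 188, 184 and 142 (fertile), but this fit takes the variation between J10 replicates, which belongs to the error of a line comparison, out of it. Stage counts were 130 and 19 in sterile J10 and 102 in sterile J03 (large against middle). Shared calls were 4 in small buds (1 higher, 3 lower), 3 in middle buds (3 lower) and 3 higher in large buds. All 168 named calls were kept, and 40 of 42 list shifts.

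Leaving out each biological replicate in turn moved 90 of 120 counts by over 1.5 times. Sterile-fertile counts ran from 2 to 17, 41 to 63 and 122 to 245 in J10 and from 0 to 1, 0 to 1 and 49 to 105 in J03. Line differences ran from 0 to 1, 0 to 13 and 2 to 17, and stage differences from 37 to 60 and 26 to 45. Line counts ran from 36 to 101, 68 to 234 and 117 to 240 (sterile) and from 8 to 21, 16 to 55 and 4 to 40 (fertile). Stage counts ran from 140 to 208 and 69 to 159 in fertile J10, 24 to 145 and 0 to 12 in sterile J10, 162 to 235 and 31 to 88 in fertile J03, and 102 to 158 and 8 to 103 in sterile J03. AMS ran from -0.23 to 0.71 in small and from -0.0194 to 0.28 in middle J10 buds, and A9 from -0.29 to 0.0759 in small J10 buds, none called.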

Other observations

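The tests in this part were chosen after the report's results were seen. The 62 probe sets lower in large sterile buds of both lines had median signals of 2387 and 1734 in the replicates of large fertile J10 buds and 2673 and 2443 in those of J03. Middle fertile J03 buds had 883 and 1077, and the replicates of the other groups 367.6 to 596.6. These probe sets were selected on the large-bud comparisons, so the contrast within large buds is no independent evidence, whereas the levels of small and middle buds played no part in the choice. In middle fertile J10 buds the medians were 506.3 and 596.6; whether the lines differ in timing was not tested.

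Hybridisations of 1 replicate were closer to each other than to the other replicate in J10, but not in J03. Of 24 J10 arrays 17 correlated best with the other hybridisation of their replicate, against 5 of 24 in J03. Mean r was 0.809 within and 0.781 between replicates in J10, and 0.799 and 0.802 in J03. Arrays of J03 with the same hybridisation number but different replicates had a mean r of 0.81. These J03 values do not bear out the reading of the titles on which the replicate means rest. No explanation for this was tested.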
